A study of Mus musculus with 6 samples.

How the data were processed

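RNA was sequenced from apoptotic osteoblasts of young and old mice, in 3 libraries per group. Per the labels' protocols, bone fragments were cultured, adherent cells were passaged and called bone marrow mesenchymal stem cells, and these were put in osteogenic medium and then killed with ultraviolet light. Total RNA was extracted with Trizol and libraries were made with a messenger RNA kit. The submitters' processing notes name the read trimmer fastp, the aligner STAR, the counter HTSeq, the package edgeR and the mouse genome build mm10, with no versions. Their parameters, the gene annotation and whether counting used strand are not given in the sources used here.

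The authors deposited a table of RPKM (reads scaled to gene length and to the total reads of the library) for 29587 gene rows, with the exon positions and a gene length for each. Multiplied by gene length, the deposited RPKM values of each library summed to 1000000, and 100.0% of them came out as whole multiples of 1 read within a tolerance of 0.01. The reads recovered in this way numbered 64881180, 77619247 and 82917726 in young replicates 1, 2 and 3 and 84535939, 75456146 and 80745726 in old replicates 1, 2 and 3. Among genes with few reads, even numbers prevailed: 77.5 to 79.3% of the genes with 1 to 5 reads had an even number. The recovered reads are therefore not independent molecules, and counting error is larger than their number implies. In a gene of 1 kilobase, 3 reads correspond to 0.0355 to 0.0462 RPKM, a floor that covers counting error only. A pair of symbols each stood on 2 rows and were told apart by chromosome, and 26 symbols had the form of a date. Coordinates are those of the deposited table on mm10, from the lowest exon start to the highest exon end of a gene.

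Replicates were compared by a chi-square test of recovered reads over genes with at least 20 reads in the pair. The statistic per degree of freedom was 482.6 and 381.2 for young replicate 1 against young replicates 2 and 3, 21.6 between young replicates 2 and 3, and 9.5 to 23.6 between old replicates, so no library was a copy of another. The labels do not say that the 3 libraries of a group came from separate animals or cultures. Limma's p-values for genes therefore measure the spread between these libraries, which may be technical.

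The group comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with group as the only term and a variance trend on mean expression. Genes entered with RPKM of at least 1 in at least 3 libraries, which left 12015. A gene that reached 1 RPKM in a single group entered through that group, so the filter itself set its direction. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05 with no minimum fold change. Every log2 fold change is old against young on the log2(RPKM + 1) scale, which understates the change of genes with low values, except where log2(RPKM + 0.1) is named. Ratios of mean RPKM carry no pseudocount.

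Before the data were examined, 31 gene lists were fixed for bone, clearance of dying cells, stress, inflammation, RNA quality and other cell types. The 26 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over these lists, and beside it with camera at an estimated correlation and with fry. At the preset correlation camera takes genes as its units, so its p-values do not measure the spread between libraries. They can be far too small where list members move together. With an estimated correlation camera rests on the residual degrees of freedom, 4 with all 6 libraries, so a call can end for that reason too. The rule for naming genes was also fixed before the data were examined. It took Cd47, the 12 genes of largest fold change in each direction among called genes whose groups did not overlap, whose higher mean reached 1 RPKM and whose symbol was not that of a predicted gene (10 passed among the lower genes), and up to 4 members of smallest p from each list, with members that describe the cells. A member of the list of restraining signals is not reported here by name.

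The alternatives set at that time were other pseudocounts (0.1 and 0.5), no filter, a mean RPKM of at least 5, 3 other scalings between libraries, other variance models, library weights, other thresholds (an adjusted p under 0.1, or a log2 fold change of at least 1), the replicate number as a block, and leaving out each library. Library weights were first estimated by restricted maximum likelihood, which did not converge, and the gene-by-gene method was taken after that was seen. A test with a count package, also set then, was not run because the deposited unit is RPKM. After the data were examined, limma's voom on the recovered reads and the removal of each library's trend on gene length and GC content (a loess fit with a span of 0.5) were added, as was camera with an estimated correlation without each library in turn. GC content came from the longest GENCODE M21 transcript of each gene, and 97% of the tested genes had a value.

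The fit was tested on simulated reads drawn from the means, depths and spread of the real libraries. At each of 4 fold sizes, 50 of the 12015 genes were changed. On the simulated values 11824 genes passed the filter, and a changed gene that did not pass counted as not recovered. The fit recovered 20% of the changes of 1.5-fold, 52% of those of 2-fold, 76% of those of 4-fold and 88% of those of 8-fold. Of the 130 genes called there, 12 had not been changed. Over 20 further simulations, 5.86% of the calls were unchanged genes, and 7.49% when the spread was taken from the old libraries alone. In a simulated shift of 1 list, that list was called and 0 of the other lists were. These simulations drew each gene independently and gave all 6 libraries the same spread. They therefore cannot show how often correlated lists are called falsely, where the estimated correlation of a real list reached 0.955 (ribosomal proteins). Nor do they cover a spread that is wider in a single library, as in young replicate 1. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.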

Results

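The data were messenger RNA profiles of mouse osteoblasts killed with ultraviolet light, from 3 libraries of young and 3 of old mice. The series concerns how apoptotic osteoblasts escape clearance by phagocytes (efferocytosis) during aging, and the comparison asks which transcripts differ with the age of the donor mice. Depth was 64881180 to 84535939 recovered reads per library, with 11242 to 12074 genes at 1 RPKM or more. The libraries expressed the type I collagen gene Col1a1 at 1550 ± 424 RPKM (SD, n = 3) in young and 1528 ± 31.8 RPKM (SD, n = 3) in old, and the osteoblast transcription factor Runx2 at 5.11 ± 0.809 and 3.91 ± 0.203 RPKM (SD, n = 3 each). Of 22 listed osteoblast genes, 14 passed the expression filter. Alpl and Bglap did not, at 0.614 ± 0.126 and 0.487 ± 0.0684 RPKM and at 0.416 ± 0.0372 and 0.742 ± 0.138 RPKM in young and old (SD, n = 3 each).

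Apoptotic osteoblasts from old mice carried more transcripts of interferon-stimulated genes, of some chemokines, and of antioxidant and glycolytic enzymes. Among surface signals that restrain phagocytes, Cd47 and class I histocompatibility genes were higher. Of 12015 genes tested with limma, 177 were higher and 12 were lower in old. Isg15, a ubiquitin-like protein induced by interferon, was at 12.3 ± 2.65 RPKM in young and 393 ± 6.23 RPKM in old (SD, n = 3 each), and Cd47, the signal that restrains engulfment through a receptor on phagocytes, was 5.51-fold higher in old. The lower genes included Sp7, a transcription factor of osteoblast differentiation, and the mitotic genes Ccnb2 and Cenpa. All 189 called genes had groups that did not overlap, which was so for 20.8% of the tested genes, where chance gives 10%.

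The number of called genes depended on which libraries were included, most of all on young replicate 1. Young replicate 1 correlated with young replicates 2 and 3 at 0.949 and 0.962 across genes, while young replicates 2 and 3 correlated at 0.996 and the old replicates at 0.995 to 0.997 (Pearson's r of log2 values, across genes that are not independent replicates). Its correlations with the old replicates were 0.959 to 0.968, so by this measure young replicate 1 was no nearer to its own group. Without young replicate 1, 1589 genes were higher and 2329 lower in old, and these included all 177 and all 12. Without young replicate 3, or old replicate 1, 2 or 3, the counts were 86, 83, 83 and 80 higher and 1, 0, 0 and 0 lower, and without young replicate 2 they were 138 higher and 2 lower. Camera with an estimated correlation called 6 gene lists with all 6 libraries. It called 0 without young replicate 1 or old replicate 2, 1 without young replicate 2, and 4 without young replicate 3 or old replicate 1 or 3, in fits with 3 residual degrees of freedom in place of 4. Mitochondrially encoded genes took 1.05% of the reads in young replicate 1, 2.126% and 2.293% in young replicates 2 and 3, and 1.616 to 1.888% in old. After removal of each library's trend on gene length and GC content, an alternative chosen after seeing the data, 241 genes were higher and 57 lower, so that 80.9% of the calls were higher in old, against 93.7% in the main comparison.

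**Figure D1:**
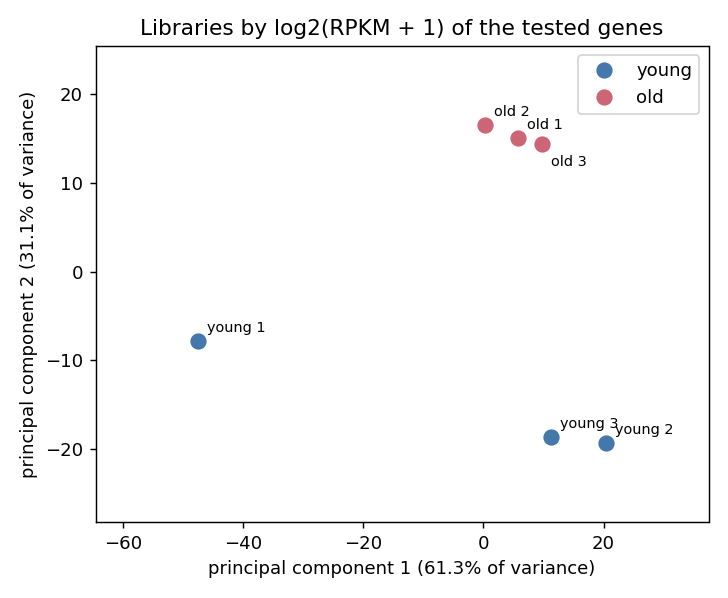
Libraries placed on the first 2 principal components of log2(RPKM + 1) over the 12015 tested genes, with young libraries in blue and old libraries in red. Young replicate 1 sits at -47.6 on the first component (61.3% of variance), the other libraries sit between 0.217 and 20.5, and the second component (31.1%) parts young from old.

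Tested surface signals that restrain phagocytes were mostly higher in old. Of 6 members tested, 4 rose (Cd47, H2-K1, H2-D1 and B2m) and Cd200 fell, and adjusted over the list alone 5 rose and 1 fell. Cd47 (chromosome 16, 49855618 to 49915010, mm10) was at 3.78, 2.64 and 2.74 RPKM in the young libraries and at 17.1, 15.8 and 17.6 RPKM in the old, a log2 fold change of 2.15 ± 0.13 (SE, limma adjusted p = 0.000662). The class I histocompatibility genes H2-K1 and H2-D1 rose by 1.67 ± 0.09 and 1.25 ± 0.08 on the log2 scale (SE, limma adjusted p = 0.00036 and 0.000946). B2m, their shared light chain, went from 89.6 ± 15.6 to 183 ± 1.33 RPKM (SD, n = 3 each), and Cd200, a ligand that restrains myeloid cells, from 9.02 ± 1.05 to 5.17 ± 0.385 RPKM. H2-K1, H2-D1 and B2m all encode chains of class I molecules and are not independent signals, and Cd47 was the only other called rise. Qpctl, Cd24a, Cd274 and Pecam1 did not pass the filter, with Qpctl at 1.15 and 0.951 RPKM and Cd274 at 0.417 and 0.532 RPKM in young and old. The list ranked higher in old than other genes (camera adjusted p = 2.59e-07, and adjusted p = 0.0261 with an estimated correlation). The calls of B2m and Cd200 were lost without any 1 of young replicates 2 and 3 and the old replicates, while those of Cd47, H2-K1 and H2-D1 held without each of the 6 libraries. Reads of H2 genes may be split among near-identical family members, so their values are uncertain.

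**Figure D2:**
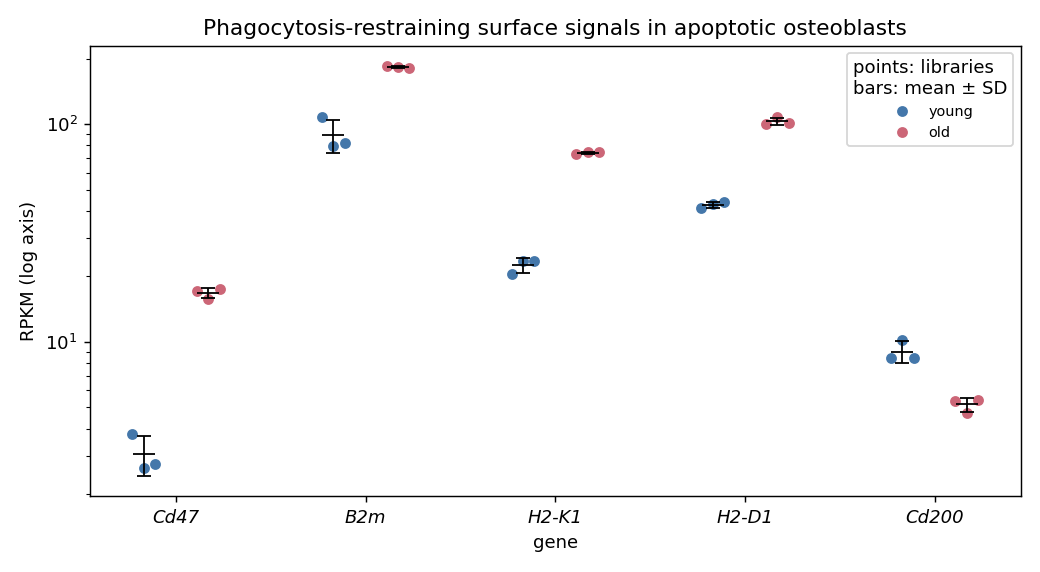
RPKM, on a log axis, of the 5 called phagocytosis-restraining signals in each library, with young libraries in blue, old libraries in red, and black bars for mean ± SD (n = 3 each). Cd47 lies between 2.64 and 3.78 RPKM in young and between 15.8 and 17.6 RPKM in old, and Cd200 is lower in old.

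Interferon-stimulated genes moved furthest. Of 22 tested members, 20 rose and 0 fell, with a median log2 fold change of 2.63, and adjusted over the list alone all 22 rose (camera adjusted p = 2.08e-62, and adjusted p = 0.0188 with an estimated correlation). With an estimated correlation the adjusted p was 0.153 without young replicate 1, 0.0535 without old replicate 2 and 0.0317 to 0.0444 without each other library. The antiviral genes Ifit1 and Oas1a went from 0.369 ± 0.145 to 14.2 ± 0.467 RPKM and from 0.0738 ± 0.0434 to 5.56 ± 0.192 RPKM (SD, n = 3 each). Both, and at least the list members Usp18, Oasl2, Irf7, Ifih1 and Zbp1, passed the filter through the old libraries alone. Passing it already made them higher in old, so their rises add no support to the count. Ifi44 went from 1.66 ± 0.157 to 22.1 ± 1.33 RPKM. The 12 named genes of largest fold change were Isg15, Ifit3, Gbp3, Ifit3b, Apol9b, Apol9a, Slfn8, Usp18, Bst2, Oasl2, Ifit1 and Ifi44, with log2 fold changes of 3.12 to 4.91, and each kept its call without each of the 6 libraries. Isg15 lies on chromosome 4 (156199424 to 156200818, mm10) and had a log2 fold change of 4.91 ± 0.15 (SE, limma adjusted p = 7.7e-05). Bst2, which tethers budding virus to the cell surface, was 15.1-fold higher in old by mean RPKM. Slfn8 also passed the filter through the old libraries alone. Ifit3 and Ifit3b, and Apol9a and Apol9b, are near-identical pairs whose reads can be split between copies, and Usp18 overlaps a predicted gene on the opposite strand, so these values are uncertain.

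Chemokines and signals that attract phagocytes rose in part. Of 22 listed chemokines and cytokines, 20 had values and 6 were tested. Of these 6, 5 rose and adjusted over the list alone all 6 rose (camera adjusted p = 1.09e-12, and adjusted p = 0.0188 with an estimated correlation). Cxcl1, Cxcl10 and Lif reached 1 RPKM in the old libraries alone, so passing the filter already made them higher in old. Ccl2, which attracts monocytes, went from 4.82 ± 1.43 to 23 ± 2.3 RPKM (SD, n = 3 each). Cxcl1 and Cxcl10 went from 0.0284 ± 0.013 to 1.98 ± 0.428 and from 0.0623 ± 0.0352 to 1.36 ± 0.211 RPKM, and Cxcl10 overlaps Art3 on the opposite strand. Of 8 find-me signals, Ccl2 and Cx3cl1 rose and adjusted over the list alone 5 rose (camera adjusted p = 0.00124). With an estimated correlation the list was not called (camera adjusted p = 0.0766). The estimate was -0.136, so correlation between the members did not end the call. The call of Cx3cl1 was lost without young replicate 3 or any old replicate, and without young replicate 1 there were 5 higher find-me signals. None of 16 eat-me signals and bridging molecules was called by limma over all genes or adjusted over the list alone. Among them Lgals3 was at 12.3 ± 4.63 and 23.5 ± 1.47 RPKM and the receptor gene Axl at 6.35 ± 3.08 and 14.9 ± 1.2 RPKM, in young and old. Without young replicate 1, 4 of these 16 were higher and 2 lower. With all 6 libraries, camera did not call the eat-me list (camera adjusted p = 0.303), but fry did (fry adjusted p = 0.0449).

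Antioxidant and glycolytic genes were higher in old. Of 15 antioxidant and metal response genes, 5 rose, 7 did so adjusted over the list alone, and the list ranked higher (camera adjusted p = 1.2e-11, and adjusted p = 0.0188 with an estimated correlation). Hmox1, which degrades heme, went from 20.8 ± 2.38 to 65.8 ± 4.02 RPKM and the quinone reductase gene Nqo1 from 10.6 ± 2.63 to 41.9 ± 3.2 RPKM (SD, n = 3 each). Of 16 glycolysis and hypoxia genes, 4 rose, 14 did so adjusted over the list alone, and the median log2 fold change was 0.51 (camera adjusted p = 3.47e-17, and adjusted p = 0.0188 with an estimated correlation). The glycolytic enzyme genes Pfkl, Eno1 and Aldoa were 1.94-fold, 1.71-fold and 1.72-fold higher by mean RPKM. The call of Pfkl was lost without old replicate 1 or 2, those of Eno1 and Aldoa without young replicate 3 or any old replicate, and that of Aldoa also without young replicate 2. Aldoa overlaps Fam57b on the opposite strand. Without young replicate 1, 13 antioxidant and 16 glycolysis genes were higher and 0 were lower. In that fit neither list was called by camera with an estimated correlation (camera adjusted p = 0.127 and 0.103).

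Proliferation genes were lower and bone genes were mixed. Of 24 cell cycle genes, Ccnb2 and Cenpa fell and 4 fell adjusted over the list alone, with a median log2 fold change of -0.26 (camera adjusted p = 4.87e-07, and adjusted p = 0.0408 with an estimated correlation). Ccnb2 went from 31.9 ± 1.3 to 21.6 ± 0.901 RPKM and Cenpa from 17.2 ± 1.09 to 10.5 ± 1.13 RPKM (SD, n = 3 each). Of 14 tested osteoblast genes, of 22 listed, Spp1 rose and Sp7 fell, and 2 rose and 2 fell adjusted over the list alone. The list was not called (camera adjusted p = 0.081), and it was called lower in 5 of 19 other settings at the preset correlation. Spp1, which encodes the matrix protein osteopontin, went from 290 ± 75.9 to 732 ± 68.6 RPKM and Sp7 from 8.44 ± 0.567 to 4.9 ± 0.0281 RPKM. Spp1 overlaps the predicted gene Gm42793 on the same strand. The other named lower genes were Otor, Fbn2, Mir7116, Trim59, Ccdc18 and Elac1, with log2 fold changes from -0.50 to -0.96. Mir7116 is a microRNA gene of 70 bases with 10, 13 and 11 recovered reads in young and 5, 6 and 6 in old, so its value is uncertain. The call of Spp1 was lost without young replicate 2 or 3 or any old replicate, and none of the 12 lower genes was called by limma without young replicate 3 or any 1 old replicate. Without young replicate 1 the osteoblast list had 2 higher and 11 lower members (camera adjusted p = 0.00907). With an estimated correlation, at 0.0212, it was not called (camera adjusted p = 0.253). In 9 of these 13 genes the left-out library lay on the old side of the midpoint between old and young replicates 2 and 3. The cell cycle list then had 14 lower members, with that library on the old side in 7. It was called at the preset correlation (camera adjusted p = 0.000275) but not with an estimated one (camera adjusted p = 0.253).

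**Figure D3:**
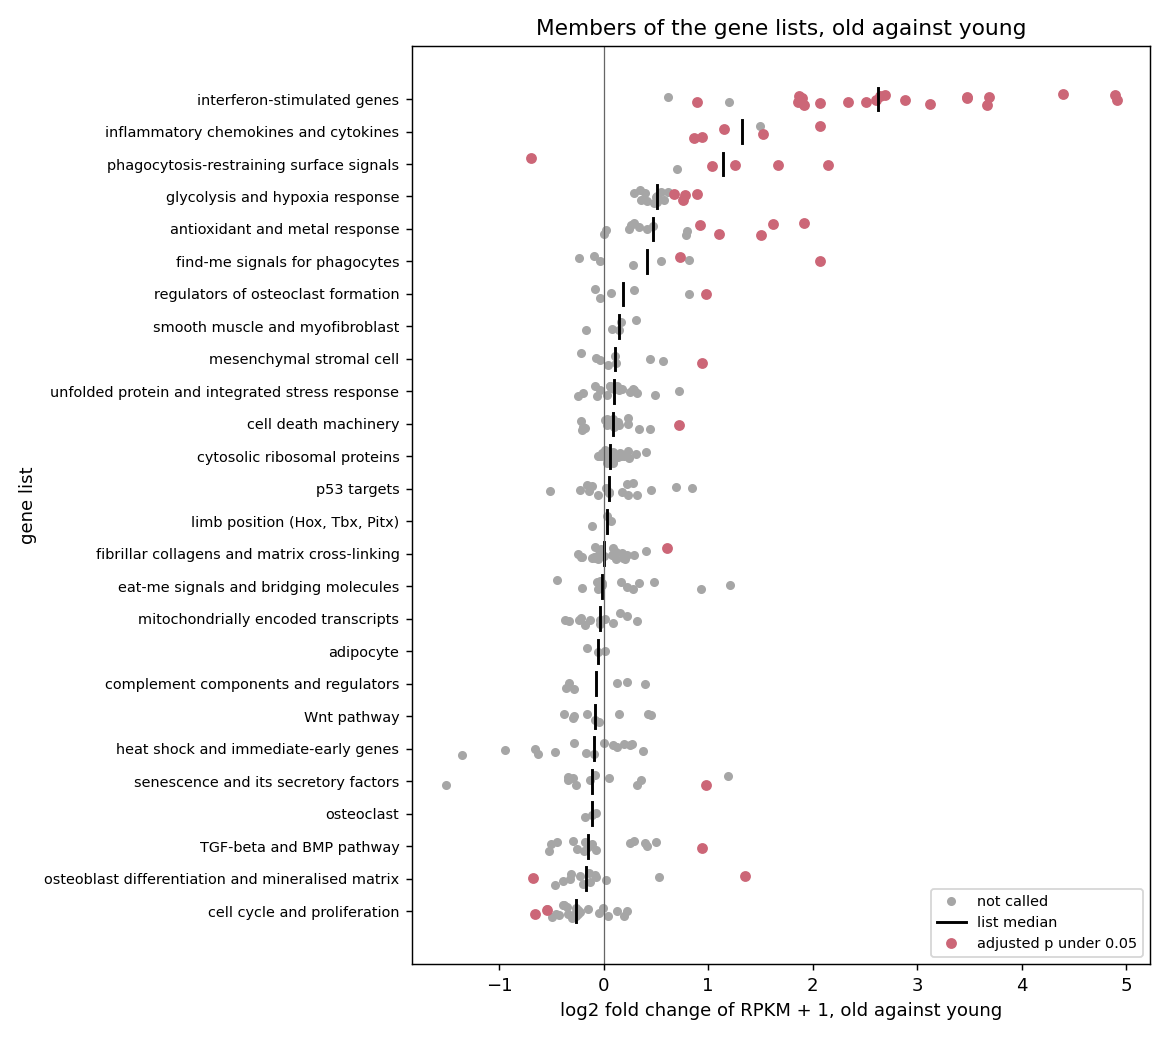
Log2 fold change of RPKM + 1, old against young, of each tested member (points) of the 26 tested gene lists, with called genes in red, other genes in grey and the list median as a black line. The interferon list has a median of 2.63 and 20 called members, and the cell cycle list has the lowest median, -0.26.

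The remaining lists were not called by camera in the main comparison, but some were under other settings at the preset correlation. The regulators of osteoclast formation (camera adjusted p = 0.0656, and adjusted p = 0.61 with an estimated correlation) ranked higher in 8 of 19 settings. Their camera adjusted p was 0.0329, 0.0361, 0.03895 and 0.0233 without young replicate 2, young replicate 3, old replicate 1 and old replicate 2. The TGF-beta and BMP list ranked lower at a mean RPKM of at least 5 (camera adjusted p = 0.00218). In the main comparison its camera adjusted p was 0.577, and 0.74 with an estimated correlation. Fas, the death receptor gene, was the 1 called gene of 19 in the cell death machinery and went from 5.84 ± 0.621 to 10.3 ± 0.811 RPKM (SD, n = 3 each), with 2 higher adjusted over the list alone. Fry called the cell death list (fry adjusted p = 0.027), and camera did not (camera adjusted p = 0.0969). Il6 was the 1 called gene among 12 tested senescence and secretory genes, of 22 listed, and among 6 regulators of osteoclast formation, at 0.702 ± 0.107 and 2.4 ± 0.746 RPKM. Il6 passed the filter through the old libraries alone, which already made it higher in old. Of the 22 senescence genes 17 were used, and the others, some commonly used markers among them, were not analysed here. Adjusted over the list alone, 4 senescence genes rose and 2 fell, and 2 osteoclast regulators rose. Grem1, an antagonist of bone morphogenetic proteins, was the 1 called gene of 9 mesenchymal stromal genes and of 17 TGF-beta and BMP genes, at 2.19 ± 0.314 and 5.14 ± 0.753 RPKM. Adjusted over the list alone, 1 stromal gene rose, and 3 of the TGF-beta and BMP genes rose and 3 fell. P4ha1, a collagen prolyl hydroxylase gene, was the 1 called gene of 25 in the collagen list, also adjusted over the list alone, at 42.8 ± 3.44 and 65.4 ± 0.327 RPKM. The calls of Fas, Il6, Grem1 and P4ha1 were lost without young replicate 2 or 3 or any old replicate. Without young replicate 1 the collagen list had 1 higher and 11 lower members, and its direction turned from higher (camera adjusted p = 0.523) to lower (camera adjusted p = 0.0271), a call that ended with an estimated correlation (camera adjusted p = 0.548). In 11 of these 12 genes the left-out library lay on the old side of the midpoint between old and young replicates 2 and 3. Without the same library, 5 cell death genes were higher and 1 lower, 4 senescence genes higher and 3 lower, 2 osteoclast regulators higher and 1 lower, 2 stromal genes higher and 2 lower, and 4 TGF-beta and BMP genes higher and 5 lower.

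Over all genes, limma called 0 of 17 p53 targets, 9 Wnt pathway genes, 19 genes of the unfolded protein and integrated stress response, 15 heat shock and immediate-early genes, 6 complement genes, 13 mitochondrially encoded genes and 35 ribosomal protein genes, with 1349 of all tested genes at an unadjusted p under 0.05. Adjusted over the list alone, 1 p53 target rose and 1 fell, 2 Wnt genes rose, 1 stress response gene rose, and 0 were called in the other 4 lists. The p53 regulator Mdm2 was at 42.3 ± 10.3 and 75.2 ± 2.5 RPKM and the immediate-early gene Fos at 44.4 ± 14.7 and 16.4 ± 4.47 RPKM in young and old (SD, n = 3 each). Young replicate 1 lay above young replicates 2 and 3 by a median of 0.81 on the log2 scale in ribosomal protein genes and below them, at -1.22, in mitochondrially encoded genes. Without it, 32 ribosomal protein genes were higher and 8 mitochondrially encoded genes were lower in old (camera adjusted p = 2.85e-15 and 0.0118), but with an estimated correlation, at 0.746 and 0.556, neither list was called (camera adjusted p = 0.379 and 0.607). The stress response list then had 6 higher and 1 lower member and ranked higher at the preset correlation (camera adjusted p = 0.0318) but not with an estimated one (camera adjusted p = 0.298). The p53 list had 4 higher and 4 lower members, the Wnt list 2 higher and 6 lower, the heat shock list 2 higher and 6 lower, and the complement list 0 higher and 3 lower, and camera called none of these 4. The Wnt list was called lower at a mean RPKM of at least 5 at the preset correlation (camera adjusted p = 0.0368). In the main comparison its camera adjusted p was 0.929, and 0.964 with an estimated correlation, at 0.81.

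Markers of other cell types gave no called gene by limma over all genes with all 6 libraries. Of the macrophage and monocyte markers, Lyz2 was tested, at 7.3 ± 0.762 RPKM in young and 8.14 ± 0.512 RPKM in old (SD, n = 3 each), and the leukocyte gene Ptprc had 6 recovered reads over all 6 libraries. None of the 6 granulocyte, lymphoid and erythroid markers with values reached 1 RPKM, the highest being Alas2 at 0.122 RPKM in old. Of 11 endothelial markers, Flt1 was tested, at 3.48 ± 0.13 and 4.99 ± 0.089 RPKM, and rose adjusted over the list alone. The 3 adipocyte, 2 chondrocyte, 3 osteoclast and 5 smooth muscle genes tested were not called over all genes or adjusted over the list alone, with Col2a1 at 40.7 ± 17 and 38.6 ± 0.897 RPKM, Ctsk at 31.8 ± 4.12 and 27.8 ± 0.991 RPKM, and Acta2 at 425 ± 2.48 and 477 ± 33.9 RPKM. Young replicate 1 decided this for several of them, with Col2a1 at 21.5 RPKM in that library and at 47.1 and 53.6 RPKM in young replicates 2 and 3. Without it, the adipocyte genes Fasn and Scd1, the chondrocyte genes Col2a1 and Sox9 and the smooth muscle gene Lmod1 were lower in old (limma adjusted p = 0.00828, 0.0351, 0.00913, 0.0244 and 0.0052), and Flt1 and the smooth muscle gene Tagln were higher (limma adjusted p = 0.00467 and 0.00798). The 3 limb position genes tested were not called either. The Y-linked genes Ddx3y and Eif2s3y were at 1.48 ± 0.572 and 1.15 ± 0.262 RPKM and at 2.22 ± 0.535 and 1.94 ± 0.118 RPKM in young and old, and Xist was at 0.122 and 0.141 RPKM.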

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

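The test with voom on recovered reads, the removal of length and GC trends, and camera with an estimated correlation without each library were chosen after seeing the data. Cd47 was called under all 21 alternatives, with log2 fold changes of 2.08 to 2.48 and limma adjusted p of 3.88e-08 to 0.0106. The main counts were 177 genes higher, 12 lower and 7 lists. A mean RPKM of at least 5 gave 99 higher, where fewer genes were tested, and a log2 fold change of at least 1 gave 106 higher and 0 lower. An adjusted p under 0.10 gave 62 lower. Library weights, which gave young replicate 1 a weight of 0.0425, gave 2119 higher, 2957 lower and 11 lists. Removal of the length and GC trends gave 57 lower. Leaving out 1 library gave 80 to 1589 higher, 0 to 2329 lower and 7 to 12 lists, the highest each time without young replicate 1. Other than for the fewer genes tested and for young replicate 1, the cause was not tested. With the replicate number as a block, 82 genes were higher, 0 lower and 8 lists were called. Deviations of same-numbered libraries from their group means correlated at -0.0257, -0.436 and 0.329, and replicate 3 alone correlated best with its own number. Young replicate 1 stood so far apart that it set most of the deviations in the young group. This check therefore cannot tell whether the numbers pair the samples. The lists for interferon, chemokines, restraining and find-me signals, antioxidants, glycolysis and cell cycle kept their call and direction in each of the 18 or 19 settings in which camera was refitted at the preset correlation. Of the other lists, the regulators of osteoclast formation were called higher in 8 of 19 settings: no filter, median-of-ratios scaling, the replicate block, the length and GC trends removed, and without young replicate 2 or 3 or old replicate 1 or 2 (camera adjusted p of 0.00482 to 0.0405). The osteoblast list was called lower in 5: a mean RPKM of at least 5, median-of-ratios scaling, library weights, the length and GC trends removed, and without young replicate 1 (0.00353 to 0.0379). The Wnt and TGF-beta and BMP lists were called lower at a mean RPKM of at least 5 alone. With library weights and without young replicate 1, the ribosomal and stress response lists were called higher and the mitochondrial list lower, and the collagen list was called lower without young replicate 1 alone. With an estimated correlation 6 lists were called, without the find-me list, and with fry 9. Fry added the eat-me list and the cell death machinery to the 7 lists of the main comparison. With an estimated correlation and a library left out, 0 lists were called without young replicate 1 or old replicate 2, 1 without young replicate 2, and 4 without young replicate 3 or old replicate 1 or 3, where fewer residual degrees of freedom remained. A test with a count package, set beforehand, was not run, because the deposited unit is RPKM. Voom gave 162 higher and 8 lower.

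Of 134 named genes, 58 were called, and 27 of these kept the call in every alternative. No called gene reversed. 11 uncalled genes changed sign in 26 cases, and the cause was not tested. With quantile normalization Fasn was at -0.0255 and Col2a1 at -0.0393. With library weights mt-Cytb was at -0.20, Fasn at -0.32, Col2a1 at -0.43, Itgb3 at 0.046, Shox2 at -0.0282 and Col1a1 at -0.24. With the length and GC trends removed Fasn was at -0.0318, Col2a1 at -0.0275 and Col1a1 at -0.0333. Over the libraries left out in turn, the log2 fold change ranged from -0.23 to 0.16 for Col1a1, -0.37 to 0.27 for Col2a1, -0.35 to 0.20 for Fasn, -0.40 to 0.15 for Scd1, -0.25 to 0.048 for Sox9, -0.23 to 0.051 for Nfatc1, -0.029 to 0.21 for Hoxc9, -0.21 to 0.011 for Itgb3, -0.047 to 0.089 for Shox2, -0.21 to 0.012 for Eif2s3y and -0.14 to 0.59 for mt-Cytb. Depth limits genes near the floor of 3 reads.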

Other observations

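The genes and families in this and the next paragraph were chosen after their values were seen, so their counts describe the data and test nothing. Beyond the fixed interferon list, all 7 tested immunity-related GTPases were higher in old, among them Irgm1, at 1.90 ± 0.469 and 11.3 ± 0.253 RPKM (SD, n = 3 each), Igtp, at 1.99 ± 0.737 and 21.97 ± 1.41 RPKM, and Iigp1, at 0.223 ± 0.154 and 6.49 ± 0.33 RPKM. Of 16 genes of antigen processing and class I presentation, 10 were higher, including the peptide transporter gene Tap1, the immunoproteasome gene Psmb9 and Nlrc5, a transactivator of class I genes, with log2 fold changes of 0.88, 0.60 and 0.80. The 16 include Psmb8, a member of the fixed interferon list, and H2-K1, H2-D1 and B2m, already counted among the restraining signals. Of 9 tested TRIM genes 7 were higher (Trim21 by 1.39 on the log2 scale), as were 5 of 6 antiviral PARP and DTX3L genes (Parp9 by 1.80). The GTPase genes Iigp1, Ifi47, Gm4841 and Gm4951, and Psmb9, Nlrc5 and Parp14, passed the filter through the old libraries alone. Passing it already made them higher in old. The calls of Tap1 and Psmb9 were lost without young replicate 2 or 3 or any old replicate, and that of Trim21 without young replicate 3 or any old replicate. Igtp overlaps Irgm2, another of the 7 GTPases, on the same strand, and on opposite strands Tap1 overlaps Psmb9, Parp9 overlaps Dtx3l and Nlrc5 overlaps 9330175E14Rik, so these values are uncertain.

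Of 10 tested genes of necroptosis and inflammatory cell death, 6 were higher in old. These were Mlkl, Casp4, Ripk2, Daxx, Fas, already counted in the cell death machinery, and Zbp1, a member of the fixed interferon list. Ripk1, Ripk3, Casp8 and Gsdmd were not called. Ripk1 was at 3.50, 6.05 and 5.40 RPKM in young and 5.20, 4.98 and 5.81 in old, and Ripk3 at 3.12, 4.24 and 4.69 in young and 4.39, 3.94 and 4.32 in old. Mlkl, the membrane-disrupting effector of necroptosis, was at 32.8 ± 1.45 and 54.8 ± 1.73 RPKM in young and old (SD, n = 3 each), and Casp4, an inflammatory caspase gene, at 1.74 ± 0.144 and 3.77 ± 0.219 RPKM, and both calls were lost without young replicate 3 or any old replicate. Irf9, the DNA-binding subunit downstream of the type I interferon receptor, was at 1.32 ± 0.418 and 8.10 ± 0.308 RPKM, and overlaps Rnf31 on the same strand, so its value is uncertain. None of 5 tested interferon receptor genes was called by limma, with 1349 of all 12015 genes at an unadjusted p under 0.05, and 2 of the 5 were higher without young replicate 1. The interferon gene Ifnb1 had 0 recovered reads in each young library and 10, 8 and 4 in the old libraries. The transcription factor gene Fosl1 was at 7.23 ± 1.68 and 33.0 ± 2.52 RPKM, and the prostaglandin synthase gene Ptgs2 at 1.22 ± 0.282 and 4.15 ± 0.576 RPKM, a call lost without young replicate 3 or old replicate 1 or 3.

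For the patterns that follow, the tests of immune cells, scaling, length and GC, depth, a wrong label and the wider spread were chosen only after related values had been seen. The count over splits and the position of the left-out library were set before their results were seen. The real split called 189 genes and the highest of the other 9 of the 10 splits of the 6 libraries called 0, and 1 of 10 splits is too few for a share under 0.05.

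The first pattern was the rise of interferon-stimulated genes in old. Immune cells in the old cultures could bring such transcripts, but the median log2 difference of 14 macrophage and monocyte markers was 0.0608 on log2(RPKM + 0.1) (SD over markers 0.116, highest 0.372 for Cd14). The tested members of the interferon list had a median of 3.94 on that scale. Most of the markers lay near 0 RPKM in both groups, where the added 0.1 keeps differences small. Adgre1, C1qb, C1qc, Fcgr1 and Mrc1 were at 0 RPKM in young and at most 0.0154 RPKM (C1qb) in old. The most abundant marker, Lyz2, was at 7.3 and 8.14 RPKM. Scaling between libraries is also argued against, since the median of the interferon list was at least 2.458 under the 3 other scalings. An effect of the age of the mice, and any handling or culture day shared by the libraries of a group, stay open, because the labels give no dates or animals.

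The second pattern was the distance of young replicate 1 from the other libraries. The SD over genes of its deviation from young replicates 2 and 3 was 3.82 times the highest of the other libraries. It was still 3.68 times after removal of the length and GC trends, and 3.73 times after all libraries were thinned to its depth, which argues against either as the whole cause. A trend was there: the deviation correlated with gene length at a Spearman's rho of -0.35 across 12015 genes, which are not independent replicates, and the removal took away 14.7% of its variance. An old sample under a young label is argued against by the interferon list alone, where young replicate 1 lay -2.57% of the way from young replicates 2 and 3 to old. That holds only if the interferon rise follows the age of the mice, which stays open. Correlations across all tested genes do not decide it, at 0.959 to 0.968 between young replicate 1 and old. With young replicates 2 and 3 they were 0.949 and 0.962. Among genes called without it, young replicate 1 lay on the old side in 80.2% of the lower and 62.7% of the higher calls. A difference in RNA quality or in the state of that culture was not tested, and no biological explanation was tested.

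The third pattern was the rise from 189 to 3918 called genes when young replicate 1 was left out. The median residual SD over genes was 2.45 times higher with that library than without it, and for each other library this ratio was at most 1.08, consistent with a wider spread in the young group as one reason for the lower count. A second candidate reason is the direction of its departure. Young replicate 1, which took no part in these calls, lay on the old side of the midpoint between old and young replicates 2 and 3 in 80.2% of the 2329 lower calls and 62.7% of the 1589 higher calls, so most of those calls part young replicates 2 and 3 from old and are not shared by the left-out library. It lay on the old side in 31 of 32 called ribosomal protein genes, 8 of 8 mitochondrially encoded genes and 11 of 12 collagen genes, in 9 of 13 osteoblast genes, 7 of 14 cell cycle genes and 5 of 13 antioxidant genes, and in 1 of 22 interferon genes and 2 of 16 glycolysis genes.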
